A study of Mus musculus with 4 samples.

How the data were processed

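Single-cell RNA was measured in 4 libraries of mouse small-intestinal epithelium, 1 per group: organoids at day 10 and mini-guts at day 10, at day 20, and at day 10 with Cryptosporidium parvum. Per the labels' protocols, days are days in differentiation medium with EGF, Noggin and R-spondin, cells were dissociated with TrypLE, and libraries were made with a 10x 3' v3 kit; the labels give no duration of infection. The deposited table holds raw UMI counts per gene and cell, with no normalization by the authors. Per the submitters' processing notes, Cell Ranger 3.0.1, Seurat 2.3.4 and the mm10 genome (GRCm38) were used. Per the file headers, each column carries its library, a cell class given by the authors and a barcode. How the authors filtered cells and named classes is not stated in the labels. The table has 16976 genes and 3570 cells, and 350 of its genes have 0 counts. Each library begins and ends at its own number of detected genes per cell, which differs between libraries, so values were also computed in the range of 3500 to 4298 genes that all 4 share. Genes are identified by symbol in the table, and positions come from GENCODE vM21, matched by symbol for 56 of 56 genes named from whole libraries.

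Cells needed at least 1000 UMIs, at least 500 genes and under 25% mitochondrial counts from 13 genes, a filter that removed 0 cells. Scrublet, as implemented in scanpy, called 1, 0, 1 and 3 doublets in the organoid, day-10, day-20 and infected libraries, and these cells were left out in an alternative only. The comparisons, gene lists, markers, rule for named genes and first set of alternatives were fixed before the data were examined. That plan named cell classes by joint Leiden clustering (2000 variable genes, 30 principal components, 15 neighbours, resolution 1, counts scaled to 10000 per cell, no batch correction). The authors' classes in the table header took its place when the table was seen, and the planned clustering became an alternative; it left 385, 285, 302 and 123 cells without a name, and its enterocyte-like cells were 37.2%, 3.85%, 14.5% and 4.75% of the libraries. The authors' classes were checked by markers at least 2-fold above all other cells: 9 of 9 for ISC, 8 of 10 for G2/M, 12 of 12 for Enterocytes, 10 of 12 for TopEnterocytes, 8 of 8 for Goblet, 9 of 9 for Paneth, 15 of 16 for Enteroendocrine, 10 of 10 for Tuft and 2 of 7 for Microfold. The Microfold class did not pass this check and is reported under the authors' name.

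Shares of cells have exact binomial (Clopper-Pearson) 95% intervals, and differences between shares have intervals built from the bounds of both shares by the square-and-add method. Gene values are counts summed over cells and divided by the library's (or class's) total UMIs, given as CPM. Ratios have 95% exact conditional intervals from the binomial distribution. Cells are not replicates, so no p-value was computed. No paired analysis was possible because each group is 1 library, and all 3 comparisons share the day-10 mini-gut library, so they are not independent of each other. A ratio against 0 counts, written as at least so many fold, is the ratio against 3 counts and can lie above the exact 95% bound, which is used only where it is named.

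Named genes are, per comparison, the 12 highest and 12 lowest by the interval bound nearest to 1, among genes with at least 100 counts and 50 CPM in at least 1 of the libraries compared. These were 2710, 2597 and 2568 genes in the 3 comparisons. Some genes that meet this rule are not reported here. Mitochondrial genes, predicted genes and genes whose symbol begins with Rpl or Rps were left out, which also drops kinases such as Rps6ka1. Within classes of at least 50 cells in both libraries, the rule took 5 genes per direction with at least 50 counts. Up to 4 members of each list with the largest bound were named too. Gene lists (29 of pathways and regions, 8 of cell class markers) were summarised by the median log2 ratio of members with at least 20 summed counts, and members at least 1.5-fold higher or lower were counted. Some genes belong to several lists. A median's place among 10000 random lists of the same size came from genes matched on expression in 20 bins. Medians of lists with members at 0 counts in 1 library were the same with these members at 3 counts. A further 7 lists of markers of other cell types and tissues were summed per library. Shares of cells with a transcript were taken after thinning each cell to 2000 UMIs, and the share in Enterocytes served as the background of free RNA.

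Alternatives were TMM factors (edgeR 4.0.16), median-of-ratios size factors (DESeq2 1.42.0), totals without mitochondrial and ribosomal protein genes, means over cells, classes weighted to the same shares, other count minimums, other cell filters, doublets left out, other clustering settings and other thinning depths. Alternatives added after the data were seen were the planned clustering, the shared range of detected genes, ISC cells alone, ratios without the cell holding most counts of a gene, and stem-like shares without clusters led by markers of another class. Simulated counts were Poisson draws from the mean profile of the libraries compared. On them, 95.7%, 95.6% and 95.3% of the intervals of unchanged genes held the true ratio in the 3 comparisons. Of genes set to a 2-fold or 4-fold difference, 86% to 100% were recovered. Such draws carry only the counting error that the intervals assume. They check the computation and not the uneven spread of counts over cells. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, scanpy 1.11.5, matplotlib 3.10.9 and R 4.3.3.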

Results

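RNA was counted in single cells of 4 mouse small-intestinal epithelial cultures, with 1 library per group. The organoid library came from conventional organoids, hollow epithelial spheres kept in Matrigel, after 10 days in differentiation medium. The other 3 libraries came from mini-guts, tube-shaped epithelia grown on a perfused microfluidic chip: after 10 days, after 20 days, and after 10 days with infection by Cryptosporidium parvum, a protozoan parasite of the intestinal epithelium. The organoid library held 998 cells and 22937992 unique molecular identifiers (UMIs, single captured RNA molecules), with a median of 23203 per cell. The day-10 mini-gut library held 961 cells and 14931803 UMIs, with a median of 14825. The day-20 mini-gut library held 1000 cells and 20427861 UMIs, with a median of 20377. The infected mini-gut library held 611 cells and 12069852 UMIs, with a median of 19106. The fewest detected genes in any cell were 3191, 2501, 2508 and 3500 in these libraries, in this order, and the most were 4595, 4298, 4996 and 4698. Median mitochondrial percentages were 9.24, 9.17, 10.3 and 9.01.

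There were no replicates, so no difference was tested, and each value describes 1 library. Every interval is a 95% interval that covers counting error only, and a count of 0 is given the bound of 3 counts, which is 0.131, 0.201, 0.147 and 0.249 CPM (counts scaled to a library total of 1000000) in the organoid, day-10, day-20 and infected libraries. Cell classes carry the authors' names from the table header, and ISC stands for intestinal stem cells. Transcripts of 7 other tissues and cell types were summed per library, in the order organoid, day 10, day 20 and infected. Pan-epithelial genes had 6239, 7047, 7517 and 7501 CPM. Fibroblast genes had 0.131, 14.5, 11.7 and 8.45 CPM, leukocyte genes 0.610, 0.402, 0.734 and 0.994 CPM, endothelial genes 6.19, 6.09, 7.88 and 11 CPM, gastric genes 0.131, 0.670, 1.42 and 0.331 CPM, and colonic genes 21.3, 43.1, 40.3 and 59.2 CPM. The table held 4 of 8 fibroblast, 5 of 9 leukocyte, 1 of 5 endothelial, 4 of 7 gastric and 5 of 6 colonic genes. None of the 5 erythroid genes was in the table.

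ISC made up 16.0% of the organoid cells (95% exact binomial interval 13.8 to 18.5), 65.0% of the day-10 mini-gut cells (61.9 to 68.1), 48.6% of the day-20 cells (45.5 to 51.7) and 61.9% of the infected cells (57.9 to 65.7). Enterocytes, the absorptive cells, made up 72.8% (70.0 to 75.6), 16.1% (13.9 to 18.6), 30.3% (27.5 to 33.3) and 16.4% (13.5 to 19.5). Dividing cells, named G2/M, made up 7.11%, 5.83%, 9.20% and 11.3%. Enteroendocrine cells, which secrete gut hormones, made up 0.301% (3 cells; 0.0620 to 0.876), 6.35% (61 cells; 4.89 to 8.08), 5.0% (50 cells; 3.73 to 6.54) and 4.91% (30 cells; 3.34 to 6.94). Paneth cells, which secrete antimicrobial peptides, made up 0.902%, 1.98%, 2.60% and 2.46%. Goblet cells made up 1.5%, 1.46%, 1.3% and 0.982%, and tuft cells 0.701%, 1.04%, 0.700% and 0.818%. The class named TopEnterocytes held 6, 14, 3 and 2 cells. The class named Microfold held 0 of 998 organoid cells, where the bound of 3 counts is 0.301% and the exact upper bound 0.369%. It held 7, 20 and 6 cells of the mini-gut libraries.

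**Figure D1:**
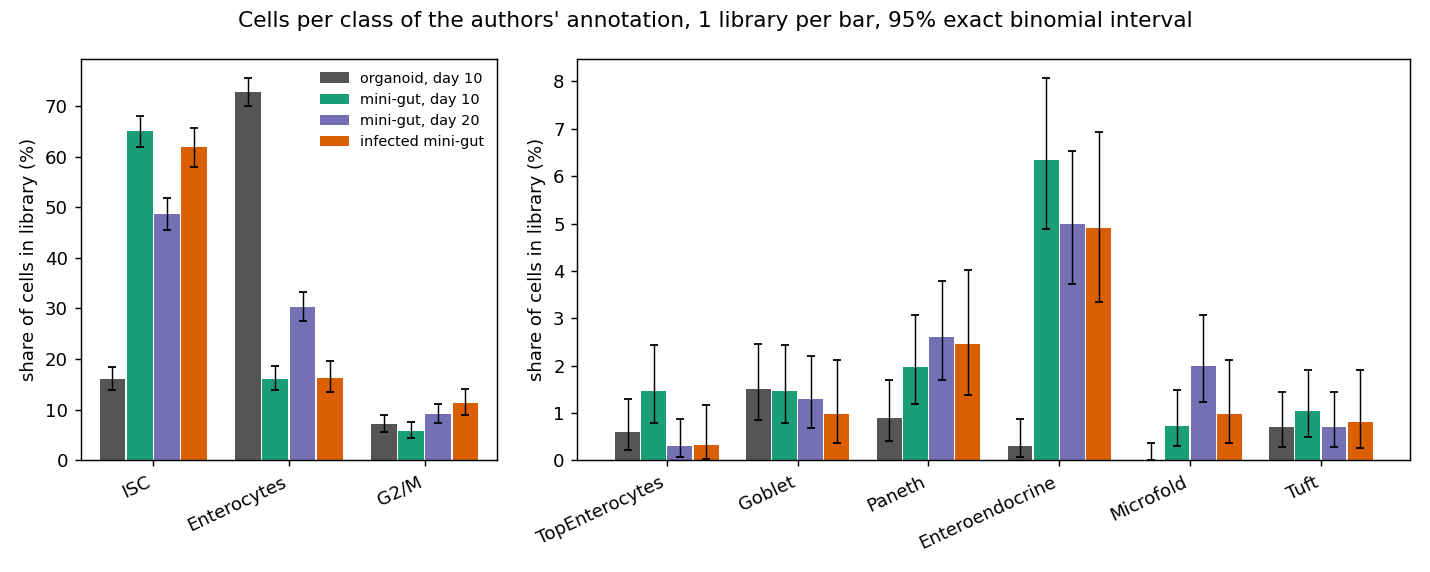
Share of cells per class of the authors' annotation in percent (vertical axes), 1 bar per library, with 95% exact binomial intervals as error bars. Enterocytes are 72.8% of the organoid cells and 16.1% of the day-10 mini-gut cells, and enteroendocrine cells are 0.301% and 6.35%.

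The comparison of the day-10 mini-gut with the day-10 organoid asks how the same epithelium differs between chip and Matrigel. The mini-gut library held fewer enterocytes, by -56.7 percentage points (-60.3 to -52.9), more ISC, by 49.0 points (45.1 to 52.8), and more enteroendocrine cells, by 6.05 points (4.48 to 7.80). Hormone transcripts were among the genes with the largest ratios: Chgb, a secretory granule protein of endocrine cells, had 1010.1 CPM in the mini-gut and 5.62 in the organoid, a 179.6-fold ratio (151 to 215). Targets of Wnt signalling, which maintains crypt stem cells, were higher in 14 of 14 measured genes, and digestive enzymes and transporters of the enterocyte brush border were lower in 21 of 22.

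Enteroendocrine genes made up 7 of the 12 genes named as highest in the mini-gut. Gcg, which encodes proglucagon (chromosome 2, 62474530 to 62483650, GRCm38), had 444 CPM against 3 counts in the organoid, a ratio of 3396 with an interval of 1162 to 16472, and 2 cells held at least 50% of its counts. Ghrl, which encodes ghrelin, was 743-fold higher (290 to 2729), with 71.0% of its counts in 1 cell, and Cck, which encodes cholecystokinin, was 93.5-fold higher (58.9 to 158), with 55.6% in 1 cell. Tac1, which encodes substance P, was 233-fold higher (139 to 427), Chga, another granule protein, was 43.9-fold higher, and Sct, which encodes secretin, was 36.1-fold higher (30.6 to 42.8). The adenosine deaminase gene Ada was 59.7-fold higher, with 96.7% of its counts in TopEnterocytes, and 2 cells held at least 50% of them. Defa22, an alpha-defensin, was 49.4-fold higher (35.1% of its counts in 1 cell, 32.1-fold without it), Ceacam10 33.6-fold and Thbs1 15.9-fold. Counts of single genes in the Defa, Reg3, Gsta, Ces1, Ugt2b, Sprr2, Ifit and Oasl families depend on how reads shared by similar paralogs were assigned.

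The 12 genes named as lowest in the mini-gut all had over 96% of their organoid counts in Enterocytes. Slc5a4b, a sodium-glucose cotransporter family gene (chromosome 10, 76057494 to 76110961), had 1.74 CPM in the mini-gut and 170.2 in the organoid, a 97.7-fold lower level (66.6 to 149.8). Mt4, a metallothionein, was 66.7-fold lower, and Ggt1, a glutathione-cleaving surface enzyme, 50.8-fold lower. Slc6a19, a transporter of neutral amino acids, was 24.4-fold lower (19.1 to 31.5), and the peptidase genes Naaladl1 and Dpep1 were 23.2-fold and 20.9-fold lower. Genes of drug and glutathione metabolism were also among the 12: Ugt2b5 was 28.2-fold lower, Gsta2 27.8-fold, Ces1f 23.3-fold and Gsta3 18.1-fold. Nat8 was 21.9-fold lower and Spink1 19.2-fold lower.

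**Figure D2:**
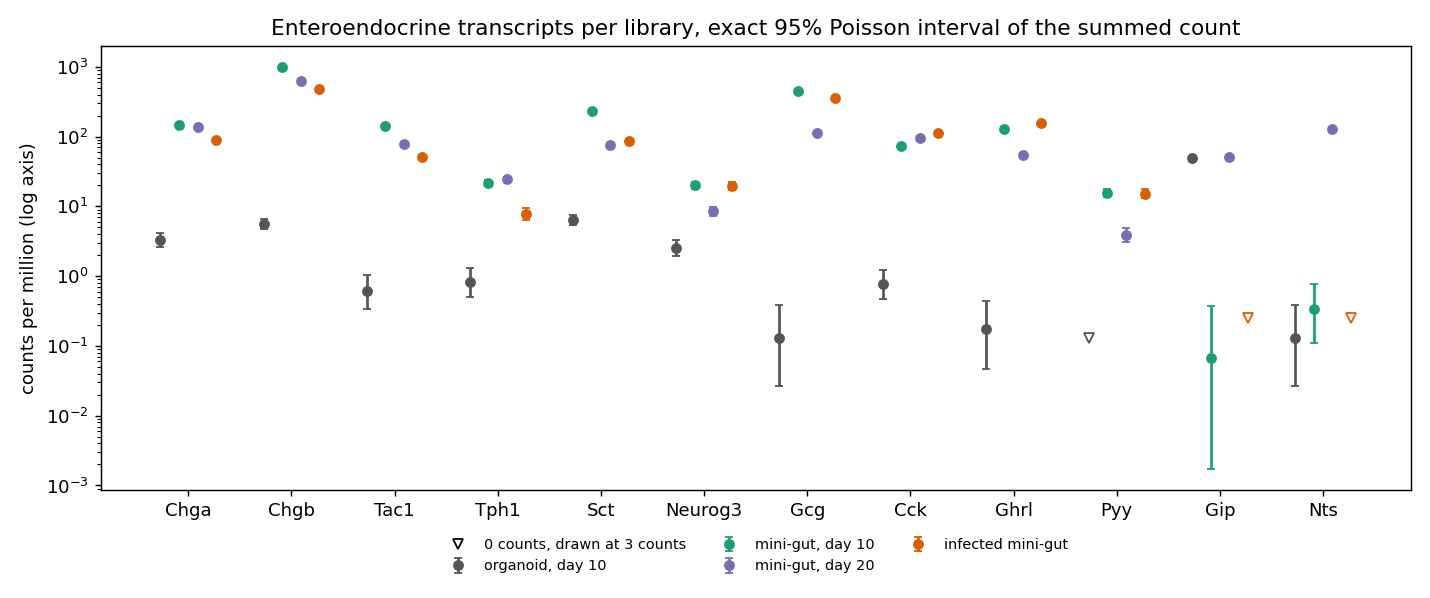
CPM (vertical log axis) of 12 enteroendocrine transcripts in each library, with exact 95% Poisson intervals of the summed count; open triangles mark 0 counts, drawn at 3 counts. Chgb is at 5.62 in the organoid library and at 1010.1 in the day-10 mini-gut library, while Gip is at 48.7 and 0.0670.

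Gene lists are given as the median log2 ratio of their measured members, with the number at least 1.5-fold higher or lower. Scaling by total counts put the median of all 12204 measured genes at 0.42 in this comparison, so list medians near that value describe no departure from the bulk of genes. Stem-like markers had a median of 2.39 (9 of 9 higher), and Wnt targets one of 2.37, with Lgr5 at 9.79-fold, Tnfrsf19 at 8.71-fold, Cd44 at 6.13-fold and Sp5 at 5.82-fold. Both medians, and that of fetal-like and regenerative genes, 2.56 (10 of 10; Clu 15.5-fold, Anxa1 22.4-fold with 33.3% of its counts in 1 cell, Msln 83.2-fold), lay above those of all 10000 random lists of matched expression. Enteroendocrine markers had a median of 5.52 (13 of 14 higher), genes of serotonin-secreting cells 5.37 (6 of 7), peptide hormones 6.55 (6 of 7), Paneth markers 1.61 (7 of 8), tuft markers 1.21 (7 of 8, a median higher than in 70.5% of the random lists), M-cell markers 2.69 (4 of 5) and goblet markers 1.02 (5 of 8, with 2 lower). Notch and secretory specification genes had a median of 1.19 (10 of 13; Neurog3 7.92-fold, Sox4 5.89-fold), BMP targets 1.60 (6 of 8; Bambi 7.21-fold, Id3 3.42-fold), and adhesion and junction genes 0.55 (9 of 18; Cldn4 10.1-fold).

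Absorptive and metabolic lists were lower in the mini-gut. Brush border genes had a median of -2.52, with Ace 15.7-fold lower, Mme 14.1-fold lower and Treh 13-fold lower, and enterocyte markers had -2.91 (12 of 12; Rbp2 13.5-fold lower, Apoa1 10.7-fold, Fabp2 8.51-fold). Xenobiotic metabolism had a median of -2.08 (18 of 21; Nqo1 15.6-fold lower, Gclc 14.2-fold), lipid absorption and oxidation -1.64 (18 of 24), cholesterol synthesis -0.87 (16 of 20; Cyp51 2.19-fold lower), iron handling -1.09 (6 of 9), hypoxia and glycolysis -0.56 (9 of 19) and oxidative phosphorylation -0.55 (9 of 22). Villus-bottom genes had -2.01 (7 of 7), proximal small-intestinal genes -1.13 (5 of 10, with 3 higher) and distal ones -1.55 (7 of 10). Antimicrobial defence had a median of -0.36, with 4 members higher and 5 lower, and Reg3a was 15.6-fold lower, Reg3b 6.87-fold and Reg3g 5.49-fold. The medians of proliferating-cell markers (-0.50), the inflammasome (-0.39), endoplasmic reticulum stress (-0.31) and the cell cycle (-0.10) also lay below the bulk of genes, at percentiles 0.05, 0.35, 1.46 and 0.24 of the random lists. Interferon gamma response had -0.01 (percentile 5.11), and YAP targets, at 0.47, lay near the bulk. The medians of the type I and III interferon response (0.19), p53 targets (0.02), villus-tip genes (0.14), dissociation stress (0.10) and NF-kappaB targets (0.42) were positive under total scaling and negative under TMM and median-of-ratios scaling, which lower every log2 ratio by 0.44 and 0.46.

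Clusters made without the authors' annotation, numbered here as found at resolution 1, split the same class differently in the 2 libraries. Of 160 organoid ISC, 67 lay in cluster 1 (stem-like) and 38 in cluster 0 (proliferating-like), and of 625 mini-gut ISC, 208 lay in cluster 13 and 169 in cluster 9 (both stem-like) and 12 in cluster 0. Clusters 3 to 6 held 719 of 727 organoid Enterocytes and 1 of 155 mini-gut Enterocytes, of which 98 lay in cluster 7 and 24 in cluster 19, neither of which could be named by its markers. Values within ISC and Enterocytes thus compare different clusters under the same class name. Within ISC, Cyp2c55 was 12.8-fold higher (9.87 to 16.8), Clps 10.8-fold, Rbpms 9.05-fold and Atf3 7.52-fold, while Gsta3 was 17.8-fold lower, Pclaf 9.73-fold (7.21 to 13.3), Prap1 6.36-fold, Fabp5 4.81-fold and Mcm5 4.25-fold. Pclaf and Mcm5 act in DNA replication, and 18 of 19 measured cell cycle genes were lower in these cells, with a median of -2.02. Wnt targets had a median of 0.63 within ISC (8 of 14 higher) and cholesterol synthesis -0.82 (14 of 20 lower). Within Enterocytes, Myl7 was 27.5-fold higher (44.7% of the counts in 1 cell), Rbpms 19.9-fold, Sprr2a3 13.3-fold (47.4% in 1 cell) and Olfm4 11.9-fold. Slc5a4b was 51.9-fold lower in Enterocytes (30.9 to 94.9), Mt4 31.1-fold, Ggt1 23.8-fold, Slc13a1 22.4-fold and Naaladl1 21.7-fold. The brush border median within Enterocytes was -1.72 (21 of 22 lower), beside 1.90 for Wnt targets (9 of 9), 3.27 for stem-like markers (6 of 6), 1.33 for fetal-like genes (6 of 6) and 1.22 for the cell cycle (12 of 16 higher). Of the 71 organoid G2/M cells, 37 lay in cluster 16 and 28 in cluster 10, against 15 and 32 of the 56 mini-gut ones. Within G2/M (56 and 71 cells), Cyp2c55 was 11.5-fold higher, Defa24 9.44-fold, Lyz1 9.28-fold and Defa30 8.90-fold, the last 3 with 65.6%, 68.2% and 62.1% of their counts in 1 cell. Among genes lower in G2/M cells, Hspa1b had 0 counts against 80, at least 15.8-fold lower but with 86.2% of the 80 in 1 cell, Dmbt1 had 1 count against 112, a ratio of 66.4 (11.7 to 2644), Aldh1a1 was 22.7-fold lower (7.58 to 112), Rbp2 8.00-fold and Maoa 5.22-fold.

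With every cell thinned to 2000 UMIs, Chgb was detected in 6.66% of mini-gut cells (64 cells; 5.17 to 8.43) and 0.301% of organoid cells, against 0.645% and 0.138% of Enterocytes, where free RNA sets the background. Before thinning, Enterocytes had medians of 21523 and 24037 UMIs in these libraries. Chga was detected in 6.24% and 0.200% of cells and in 0% of Enterocytes, Sct in 6.24% and 1.70% against 0.645% and 1.24% of Enterocytes, and Neurod1 in 4.16% and 0%, with 0% of Enterocytes. Tac1 was detected in 4.37% of mini-gut cells and in 0 of 998 organoid cells, which allows up to 0.301% of cells with a UMI at that depth; before thinning, 2 organoid cells held a Tac1 UMI. Gcg was detected in 0.937% of mini-gut cells and in 1.29% of the 155 Enterocytes, too few cells to tell its share from background. Before thinning, 99.7% of its counts lay in enteroendocrine cells. Mmp7, a Paneth cell protease, was detected in 4.58% and 0.902%, with 0% of Enterocytes. Clustering without the authors' annotation gave differences in the enterocyte share between -33.1 and -61.4 points across its settings. With the classes weighted to the same shares in both libraries, the Wnt median was 0.67 and the brush border median -1.37, and the brush border median within ISC was -0.02.

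**Figure D3:**
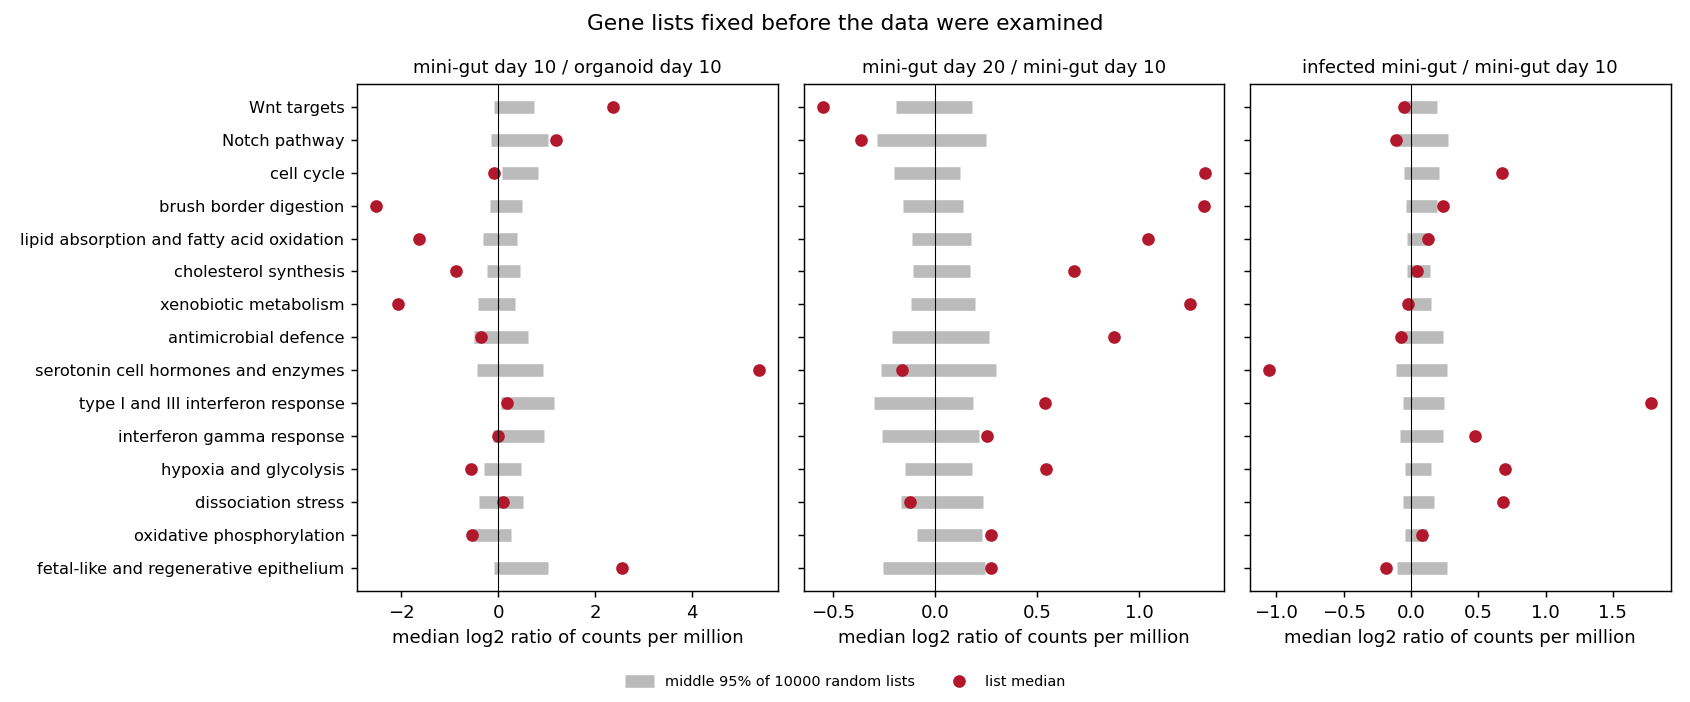
Median log2 ratio of CPM (horizontal axis) of 15 gene lists in the 3 comparisons; points are lists and grey bars hold the middle 95% of 10000 random lists of matched expression. The Wnt median is 2.37 in the mini-gut against the organoid, the cell cycle median is 1.32 at day 20 against day 10, and the interferon median is 1.79 in the infected library.

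The comparison of the day-20 with the day-10 mini-gut asks how the tissue on the chip differs with age. The day-20 library held more enterocytes, by 14.2 percentage points (10.4 to 17.9), and fewer ISC, by -16.4 points (-20.8 to -12.0). Among cells in the range of detected genes shared by all libraries, these differences were 3.71 points (-2.49 to 9.97), an interval that holds 0, and -7.07 points (-13.9 to -0.141). That range kept 108 of the 303 day-20 Enterocytes but 125 of the 155 at day 10, so it removed this class unequally. No day-10 cell had more than 4298 detected genes, while day-20 cells reached 4996 and day-20 Enterocytes had a median of 4388. The differences over all cells thus also compare unlike ranges of detected genes. In the shared range, G2/M cells made up 6.17% at day 10 and 7.90% at day 20. Clusters made without the authors' annotation gave larger ISC differences, of -21.2 points at resolution 1 and -30.5 at resolution 0.5. Enterocyte genes were higher, among them Apoa4, an apolipoprotein of dietary fat transport (chromosome 9, 46240696 to 46243459), at 701 CPM against 158, a 4.42-fold ratio (4.24 to 4.62). All 20 measured cell cycle genes were at least 1.5-fold higher, with a median log2 ratio of 1.32, and 7 of 14 Wnt targets were lower.

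Among the 12 genes named as highest at day 20, 9 had most of their counts in Enterocytes: the antimicrobial genes Leap2 (6.71-fold) and Reg3a (5.46-fold, 5.05 to 5.90), Mt4 (6.17-fold), Ugt2b5 (5.69-fold), Gsta2 (5.49-fold), Adh1 (5.06-fold), Ces1f (4.82-fold), Gsta3 (4.70-fold) and Apoa4. The other 3 rested on very few cells. Nts, which encodes neurotensin, was 381-fold higher (163 to 1173) with 78.8% of its counts in 1 cell, and Gip, which encodes an incretin hormone, had 51.6 CPM against 1 count, a ratio of 771 (138 to 30488) with 95.3% in 1 cell. Crct1, a gene of cornified epithelia, was 175.7-fold higher (98.0 to 352), with 96.1% of its counts in the Microfold class and 36.5% in 1 cell. The genes named as lowest included the hormones Gcg (3.89-fold lower), Sct (3.07-fold) and Ghrl (2.37-fold, higher at day 20 once the day-10 cell with 71.0% of its counts is left out), and the defensins AY761184 (3.89-fold) and Defa24 (2.13-fold). Ada was 3.94-fold lower, Clps, a pancreatic lipase cofactor, 3.60-fold, and Ceacam10 3.14-fold. Pdgfa, a growth factor gene counted in 890 day-10 cells, was 2.18-fold lower, Stra6l 2.18-fold, and Ifitm3 and Fxyd3 2.09-fold each.

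The median of all genes lay at -0.03 under total scaling. Among the cell cycle genes, Rrm2 was 4.77-fold higher, Top2a 3.57-fold, Cdk1 3.55-fold and Birc5 3.24-fold, and markers of proliferating cells had a median of 1.41 (10 of 10). Brush border genes had a median of 1.32 (17 of 22; Lct 9.11-fold, Slc6a19 5.92-fold, Slc2a2 4.19-fold, Treh 4.10-fold) and enterocyte markers 1.74 (12 of 12). Lipid absorption had 1.04 (18 of 25; Apoc3 4.24-fold, Fabp1 3.57-fold, Apoa1 3.49-fold), xenobiotic metabolism 1.25 (17 of 21; Nqo1 4.55-fold, Aldh1a1 4.31-fold) and cholesterol synthesis 0.68 (13 of 20). Proximal genes had 1.63 (7 of 10), distal genes 0.99 (6 of 9), villus-bottom genes 1.31 (5 of 7) and antimicrobial defence 0.88 (7 of 12; Reg3b 2.75-fold, Reg3g 2.5-fold, Lyz1 1.80-fold). YAP targets had 0.97 (6 of 10), hypoxia and glycolysis 0.54 (7 of 19), the type I and III interferon response 0.54 (11 of 23; Isg15 14.6-fold, with 35.0% of its 80 counts in 1 cell), iron handling 0.50 (3 of 9), tuft markers 0.43 (4 of 8) and NF-kappaB targets 0.38 (8 of 17). Medians between 0.20 and 0.28 were those of interferon gamma response, p53 targets, oxidative phosphorylation, the inflammasome and fetal-like genes, and medians from -0.16 to 0.09 those of endoplasmic reticulum stress, BMP targets, villus-tip genes, adhesion, M-cell markers, dissociation stress and serotonin-cell genes. Lower lists were peptide hormones at -1.24 (5 of 8), enteroendocrine markers at -0.71 (8 of 15), stem-like markers at -0.61 (5 of 9; Smoc2 1.96-fold lower), Wnt targets at -0.55 (Lgr5 1.86-fold lower, Sox9 1.67-fold), Paneth markers at -0.49 (2 lower and 2 higher of 9), goblet markers at -0.37 (1 lower and 2 higher of 8) and Notch genes at -0.36 (4 of 13).

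Of the 486 day-20 ISC, 127 lay in cluster 8 (unnamed) and 64 in cluster 13, against 148 and 208 of the 625 at day 10. The proliferating-like cluster 0 held 66 day-20 ISC against 12, and cluster 2, led by DNA replication genes, 56 against 15. Of the 303 day-20 Enterocytes, 130 lay in cluster 11 (enterocyte-like) and 99 in cluster 7, against 19 and 98 of the 155 at day 10. Within ISC, Pclaf was 9.68-fold higher (7.35 to 13), Mcm5 4.10-fold, Prap1 3.97-fold, Fabp5 3.30-fold and Hells 3.24-fold, and the cell cycle median was 1.57 (20 of 20). Cholesterol synthesis had 0.90 in these cells (12 of 20) and hypoxia and glycolysis 0.73 (13 of 19), while Wnt targets had -0.22. Clps was 5.58-fold lower in ISC, Pla2g1b 4.03-fold, Cyp2c55 2.22-fold and Pdgfa 1.96-fold. In Enterocytes, Slc5a4b was 15.5-fold higher (9.18 to 28.6), Ggt1 12.1-fold, Tff3 9.36-fold (53.6% of its counts in 1 cell), Papss2 7.82-fold and Cyp2c29 6.55-fold, and Olfm4 was 4.39-fold lower, Sprr2a3 3.16-fold (1.68-fold without 1 day-10 cell), Nupr1 3.06-fold, Smoc2 2.52-fold and Sox4 2.13-fold. Their brush border median was 1.35 (20 of 22), with 1.05 for xenobiotic metabolism (18 of 21), 0.97 for lipid absorption (17 of 25), 0.86 for the interferon response (9 of 16) and -0.47 for Wnt targets. Of the 92 day-20 G2/M cells, 52 lay in cluster 16, whose leading genes include Esco2 and Hist1h1b, and 31 in cluster 10. At day 10 these clusters held 15 and 32 of the 56. Values within G2/M thus also compare different mixtures of clusters. In G2/M (92 and 56 cells), Fbxo5 was 7.43-fold higher, Esco2 4.32-fold, Hist1h1b 3.90-fold, Pbk 3.86-fold and Cdk1 3.28-fold, and Tff3 was 9.19-fold lower, Spink4 4.36-fold and Cyp2c55 2.76-fold. Lyz1 and Defa24 were 2.85-fold and 2.84-fold lower in G2/M only through 1 day-10 cell with 68.2% and 65.6% of their counts, and 1 cell also held 54.5% of the Tff3 and 45.3% of the Spink4 counts. Enteroendocrine cells (50 and 61) differed in Nts (2555 counts against 0, at least 951-fold higher), Gip (1007 against 1; ratio 1125, 201 to 44471), Sbpl (78 against 0, at least 29.0-fold) and Olfm4 (21.5-fold), where 1 cell held 80.3%, 99.8%, 94.9% and 35.4% of the counts, and in lower Lyz1 (5.53-fold), Hdc (4.64-fold), Ceacam10 (3.03-fold), Clps (2.85-fold) and Gcg (2.55-fold). After thinning, Chgb was detected in 4.90% of day-20 cells against 0.330% of Enterocytes, and Chga in 4.4% against 0%. Among cells in the shared range of detected genes, the brush border median was 0.59 and the cell cycle median 0.49. The brush border median within ISC was 0.02, and the directions of Tff3, Cyp2c29 and Nupr1 in Enterocytes reversed in cells taken from clusters made without the authors' annotation.

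The comparison of the infected with the day-10 mini-gut asks how the epithelium differs with the parasite. Genes of the type I and III interferon response were higher in the infected library, 26 of 28 by at least 1.5-fold with a median log2 ratio of 1.79, led by Oasl2, Rtp4 and Isg15. Fabp6, the ileal bile acid-binding protein (chromosome 11, 43596049 to 43601540), had 104 CPM against 1 count, a ratio of 1555 (279 to 61470), and Slc51b, a subunit of the bile acid exporter of enterocytes (chromosome 9, 65412714 to 65422955), was 12.3-fold higher (9.53 to 16.0). Transcripts of serotonin-secreting cells were lower in 6 of 7 genes. The libraries held 30 infected and 61 day-10 enteroendocrine cells, and 30 is below the 50 cells set for naming genes within a class. Tph1 had 95 infected counts in 8 cells. At day 20, Chgb (618 CPM against 1010) and Tac1 (77.8 against 142) were also lower than at day 10, while Tph1 was not (24.5 against 21.7). The enterocyte share differed by 0.238 points (-3.54 to 4.14) and the ISC share by -3.17 (-8.17 to 1.79), both with intervals that hold 0. Among cells in the shared range of detected genes, the differences were -13.8 (-18.9 to -8.62) and 7.85 (1.29 to 14.3), so their size and sign depend on which cells are compared. That range kept 49 of the 100 infected Enterocytes but 125 of the 155 at day 10. Infected cells reached 4698 detected genes, and infected Enterocytes had a median of 4325, above the day-10 maximum of 4298.

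Fabp6 was counted in 45 infected cells, 2 of which held at least 50% of the counts, and 97.2% of its counts lay in Enterocytes. Slc51b was lowest at day 10, with 67 counts, and had 778 in the organoid, 279 in the day-20 and 664 in the infected library. Ifi27, an interferon-induced gene (chromosome 12, 103434211 to 103440239), was 3.76-fold higher (3.38 to 4.18) over 425 cells, and Bst2, which encodes the antiviral protein tetherin, was 2.48-fold higher. The immediate early genes Egr3, Arc and Egr2 were 5.47-fold, 3.37-fold and 3.08-fold higher. Slc16a3, a lactate exporter, was 3.13-fold higher, Ankrd37 3.01-fold and Ero1l 2.69-fold, all 3 known as hypoxia-responsive, and Adh6a was 4.21-fold and Acta1 2.49-fold higher. The genes named as lowest began with Ada, at 5.88 CPM against 164, 27.9-fold lower (22.0 to 35.8), a gene that 2 day-10 cells held to at least 50%. Lower Paneth and goblet products were AY761184 (3.80-fold), Defa30 (2.53-fold), Defa21 (1.94-fold, with 56.6% of its day-10 counts in 1 cell, and reversed when each cell weighs the same) and Spink4 (1.93-fold). Clu was 3.25-fold lower, Reg1 3.14-fold (2.24-fold without 1 day-10 cell), Clps 2.80-fold and Sprr2a3 2.15-fold (1.22-fold without 1 day-10 cell), and the endocrine genes Tac1, Sct and Chgb were 2.78-fold, 2.63-fold and 2.07-fold lower. Ada, AY761184, Clps and Sct were also among the genes named as lowest at day 20.

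**Figure D4:**
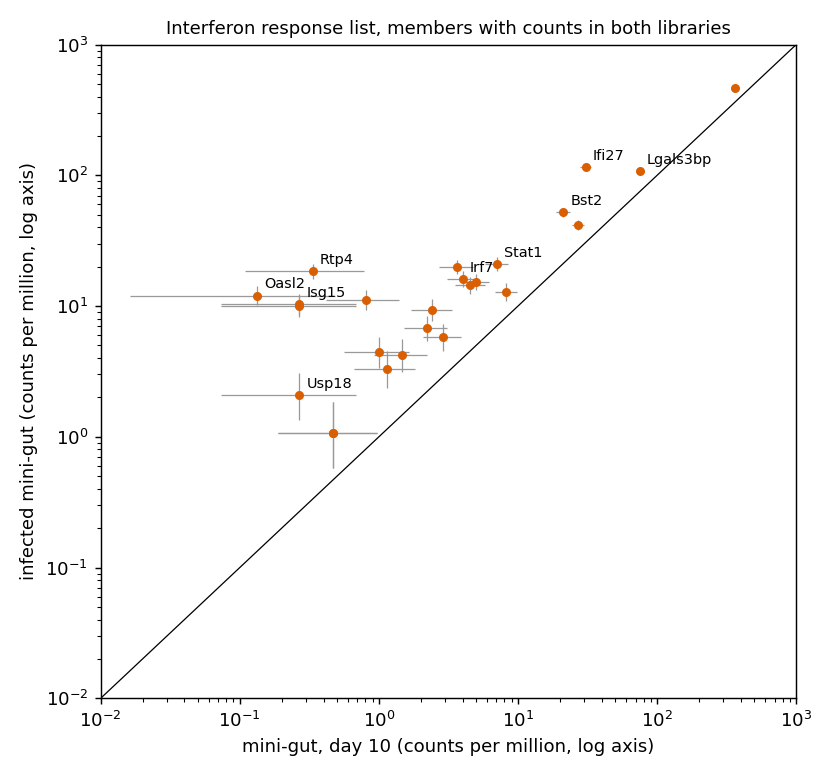
CPM of the 25 members of the type I and III interferon list counted in both libraries, day-10 mini-gut (horizontal log axis) against infected mini-gut (vertical log axis), with exact 95% Poisson intervals and the line of equal values. All 25 members lie above the line, with Ifi27 at 30.7 and 115.

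The median of all genes was 0.07 under total scaling. In the interferon list, Rtp4 had 18.4 CPM against 0.335, a ratio of 54.9 (23.2 to 171). Oasl2 had 12 CPM against 2 counts, a ratio of 89.7 (24.4 to 748). Isg15 had a ratio of 38.7 (14.7 to 144), and Ifit3 had 68 counts against 0. In the infected library, Ifit3 was counted in 10 cells, with 33.8% of its counts in 1, and Isg15 in 45 cells, with 29.6% in 1. Rtp4 was counted in 121 infected cells and Oasl2 in 69. The interferon gamma response had a median of 0.47 (6 of 15; Igtp 4.77-fold, Cxcl10 4.75-fold with 39.8% of its infected counts in 1 cell, Irgm1 2.87-fold, Tap1 2.83-fold). Class II antigen presentation genes, too few for a median, summed to 6.79 CPM against 3.68. Hypoxia and glycolysis had a median of 0.70 (13 of 19, with Adm at 3.63-fold and Egln3 at 2.5-fold). Dissociation stress had one of 0.69 (9 of 15, with Atf3 at 2.22-fold, Ier3 at 1.92-fold, Junb at 1.88-fold and Dusp1 at 1.84-fold). That list was meant to track sample handling, but whether handling raised these genes here was not tested. YAP targets had 0.89 (6 of 9; Ereg 2.97-fold, Cyr61 2.09-fold, Areg 1.85-fold), the cell cycle 0.68 (12 of 20; Ccnb1 2.33-fold, Ccnb2 2.23-fold, Top2a 2.03-fold) and proliferating-cell markers 0.71 (6 of 10). Distal small-intestinal genes, a list that holds Fabp6 and Slc51b, had 1.27 (5 of 9), proximal genes 0.31 (4 of 10), tuft markers 0.55 (4 of 8), iron handling 0.33 (4 of 9; Cybrd1 6.93-fold with 42.9% in 1 cell, Slc40a1 4.38-fold) and NF-kappaB targets 0.39 (4 of 15; Cxcl1 3.76-fold, Tnf 2.19-fold). Against day 10, the uninfected day-20 library also had positive medians for hypoxia and glycolysis (0.54), YAP targets (0.97), the cell cycle (1.32) and proliferating-cell markers (1.41). The same held for distal (0.99) and proximal genes (1.63), tuft markers (0.43), iron handling (0.50), NF-kappaB targets (0.38) and the interferon gamma response (0.26). The type I and III interferon response was positive too, at 0.54 (11 of 23 higher), below its 1.79 in the infected library. Isg15 had 80 counts at day 20 against 4 at day 10, Rtp4 35 against 5 and Oasl2 23 against 2. Higher medians of these lists are thus not particular to the infected library, while dissociation stress had -0.12 at day 20. Serotonin-cell genes had a median of -1.05 (Tph1 2.76-fold lower, Chga 1.64-fold), goblet markers -0.62 (3 of 6 lower), Paneth markers -0.39 (3 lower and 2 higher of 9), enteroendocrine markers -0.34 (6 of 13), fetal-like genes -0.19 (4 of 10) and peptide hormones -0.03. The lists of brush border genes (0.24), M-cell markers (0.17), lipid absorption (0.13), p53 targets (0.11), endoplasmic reticulum stress (0.10) and enterocyte markers (0.10) lay near 0, and so did oxidative phosphorylation, BMP targets, cholesterol synthesis, stem-like markers, adhesion, villus-tip and villus-bottom genes, the inflammasome, xenobiotic metabolism, Wnt targets, antimicrobial defence and Notch genes, with medians from -0.11 to 0.08.

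Of the 378 infected ISC, 154 lay in cluster 9 and 73 in cluster 18 (both stem-like), against 169 and 0 of the 625 at day 10, and of the 100 infected Enterocytes, 36 lay in cluster 19, 27 in cluster 11 and 22 in cluster 7, against 24, 19 and 98 of the 155 at day 10. Within ISC, the interferon median was 2.12 (22 of 22). It was not even among them: cluster 18, which is led by interferon-induced genes and held infected cells only, had a median of 3.44 in its 73 ISC, and the other 305 infected ISC had 0.83. Both values depend on the choice of these cells by the same genes, and the cluster depends on the settings. At resolution 2 a cluster of 72 cells was infected only, and with 1000 variable genes 85 of 86 cells of 1 cluster were infected, while no such cluster was found at resolution 0.5, with another seed, with doublets left out or after thinning. Among ISC, Egr3 was 5.57-fold higher, Ifi27 4.28-fold (3.73 to 4.93), Arc 3.93-fold, Egr2 3.78-fold and Rasd1 3.14-fold. In ISC, dissociation stress had 0.74 (11 of 15), YAP targets 0.89 (6 of 8) and hypoxia and glycolysis 0.53 (8 of 19). Clps was 4.64-fold lower in ISC, Defa30 3.23-fold, Defa24 3.16-fold, Spink4 2.04-fold and Car8 1.94-fold. Paneth cells held 86.0% of the day-10 counts of Defa30, 80.6% of those of Defa24 and 66.8% of those of Spink4. No background of free RNA was taken for these genes in ISC. Enterocytes had 1222 Fabp6 counts against 0, at least 518-fold higher, with Slc51b 17.7-fold higher (13.1 to 24.5), Oasl1 9.60-fold, Pdlim2 8.51-fold and Gda 7.66-fold. Ctrb1, a pancreatic protease precursor, was 20.6-fold lower in Enterocytes (40.8% of its counts in 1 cell), Reg1 3.05-fold, Reg3b 2.98-fold, Bmp3 2.67-fold and Sprr2a3 2.18-fold (1.16-fold without 1 day-10 cell). Enterocyte medians were 2.47 for the interferon response (17 of 20), 2.23 for distal genes (6 of 8), 1.08 for villus-tip genes (7 of 9), 1.05 for hypoxia and glycolysis (19 of 19) and 0.90 for interferon gamma response (8 of 11). In G2/M (69 and 56 cells), Cxcl10 had 91 counts against 0, at least 19.2-fold higher but with 85.7% of the counts in 1 cell, Ifi27 was 5.11-fold higher, Ankrd37 3.69-fold, Hist1h1c 2.83-fold and Btg2 2.47-fold, and the interferon median was 0.86 (7 of 8). Spink4 was 3.89-fold lower in G2/M, Sis 2.54-fold and Prap1 2.16-fold, while Defa30 (3.16-fold lower) and Defa24 (2.36-fold lower) had 62.1% and 65.6% of their day-10 counts in 1 cell, and without it Defa30 was 1.22-fold lower and Defa24 higher. After thinning, Chgb was detected in 3.93% of infected cells and 0% of Enterocytes, Tac1 in 2.29% against 4.37% at day 10 and Tph1 in 0.982% against 1.98%, with 0% of Enterocytes for both genes. Lyz1, the Paneth cell lysozyme, was detected in 3.60% against 5.62%, beside 0% and 1.29% of Enterocytes, which had a median of 26122 UMIs in the infected library before thinning. Its level went the other way, with 311 CPM in the infected library against 160 at day 10. In each library 1 cell held a large part of the Lyz1 counts, 22.4% and 32.9%. The directions of Oasl1 and Sprr2a3 within Enterocytes reversed in cells taken from clusters made without the authors' annotation.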

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

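The alternatives chosen after the data were seen are clustering at resolution 1, stem-like cells without clusters led by another class's markers, the range of detected genes shared by all libraries, ISC alone and ratios without the cell holding most counts of a gene; the 7 share differences and 6 list medians followed most closely were also picked then. No library could be left out, as each group has 1. Leaving out doublets, the stricter cell filter and keeping all barcodes moved no share difference, median or ratio that they were run on with the authors' classes. The last 2 removed or added 0 cells and so say nothing. Clustering with doublets left out did differ, as it held no cluster of infected cells only. The difference in enteroendocrine share stayed within its interval in all 10 alternatives, 2 of which (stricter filter, all barcodes) could not move it. Of 576 values of named genes' log2 ratios, 414 stayed within their interval, 159 moved and 3 reversed. The 414 include 72 values with all barcodes, which could not move. Within classes, 281 of 380 stayed, 92 moved and 7 reversed. Ratios with 0 counts in 1 library have no log2 value and were not followed. Of 372 shares of cells with a transcript, 166 moved, most often with unthinned counts (76 of 124), so these shares depend on depth. The cause of most moves below was not tested. TMM and median-of-ratios factors shift every ratio of a comparison alike, and cells of unnamed clusters drop out of the enterocyte-like share.

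The enterocyte difference between mini-gut and organoid at day 10 was -51.1 points in the shared gene range and, by clustering, -33.3 at resolution 1, -33.1 at 0.5, -35.7 at 2, -40.9 with 1000 variable genes, -35.5 with another seed and -61.4 after thinning. At resolution 1, the unnamed clusters 4 and 5 held 115 and 241 of the 727 organoid Enterocytes. The unnamed clusters 7 and 19 held 98 and 24 of the 155 mini-gut ones. The difference at resolution 1 thus depends on which clusters could be named. Between day 20 and day 10 the enterocyte difference was 3.71 points in the shared range and 10.1 at resolution 0.5, and between infected and day 10 it was -13.8 in the shared range. The shared range kept 125 of 155 day-10, 108 of 303 day-20 and 49 of 100 infected Enterocytes. Its upper end is the day-10 maximum of 4298 genes, so the differences over all cells also compare unlike ranges of detected genes. The ISC difference between mini-gut and organoid was 43.8 points in the shared range and, by clustering, 37.8 at resolution 1, 53.8 at 0.5, 37.7 at 2 and 44.5 after thinning. Between day 20 and day 10 it was -7.07 in the shared range, -21.2 at resolution 1, -30.5 at 0.5, -27.7 with 1000 variable genes, -29.1 with another seed and -27.2 after thinning. Between infected and day 10 it went from -3.17, whose interval holds 0, to 7.85 in the shared range, 5.44 at resolution 1 and 6.61 at 2. Resolutions 1 and 2 each named 1 cluster stem-like that had more markers of dividing than of stem cells among its top 10 genes; without it the 3 differences were 36.2, -25.1 and 2.04 at resolution 1 and 36.0, -24.3 and 5.27 at 2. In the first comparison, the Wnt median was 1.94 with TMM, 1.91 with median-of-ratios factors, 0.67 with weighted classes and 0.63 in ISC, and the brush border median was -2.96 with TMM, -2.98 with median-of-ratios factors, -2.78 as a mean over cells, -1.37 with weighted classes, -2.20 in the shared range and -0.023 in ISC. For day 20, the brush border median was 1.18 as a mean over cells, 0.90 with weighted classes, 0.59 in the shared range and 0.023 in ISC, and the cell cycle median was 0.89 with weighted classes, 0.49 in the shared range and 1.57 in ISC. For infection, the interferon median was 1.66 with at least 100 counts, 2.21 in the shared range and 2.12 in ISC, and the hypoxia median was 0.62 with either TMM or median-of-ratios factors, 0.66 as a mean over cells, 0.47 in the shared range and 0.53 in ISC. The log2 ratio of Defa21 for infection reversed to 0.12 as a mean over cells and to 0.25 without 1 cell. Also without 1 cell, that of Ghrl at day 20 reversed to 0.54, and within G2/M those of Lyz1 at day 20 (0.10) and Defa24 with infection (0.26). In Enterocytes taken from clusters at resolution 0.5, log2 ratios reversed for Tff3 (-0.69), Cyp2c29 (-0.49) and Nupr1 (0.19) at day 20 and for Oasl1 (-0.029) and Sprr2a3 (0.27) with infection. Depth limits genes near the bound of 3 counts and classes of few cells.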

Other observations

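The tests chosen after the result was seen are those of a library difference unrelated to infection and of a more distal identity; the gene sets of the next 2 paragraphs were also picked after their values were seen.

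The class that the authors named Microfold held 33 cells, all from mini-guts. Of 7 M-cell markers, 2 were at least 2-fold higher than in other cells, Tnfrsf11b at 8.36-fold and Marcksl1 at 4.34-fold. Ccl20 and Ccl9 had ratios of 0.865 (0.559 to 1.28) and 0.277 (2 counts; 0.0335 to 1.003). Spib, Tnfaip2 and Ccl6 had 0 counts, with exact 95% upper bounds of the ratio at 7.47, 7.61 and 1.35, so Spib and Tnfaip2 are too rare here to speak for or against M cells. All 11 fetal-like and regenerative genes were at least 2-fold higher in these cells, with a median of 5.65, and so were 9 of 10 YAP targets, with a median of 3.29. Among their genes were Crct1 (4071 CPM against 1.66), Msln (1098 against 3.79), Ctgf (806 against 2.19), Fn1 (611 against 0.703) and Ptgs2 (497 against 0.473). All 12 enterocyte markers were at least 2-fold lower, with a median of -5.34, and stem-like markers had a median of -1.11.

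Transcripts of pancreatic digestive proteins were present in all 4 libraries and did not move together. Clps had 41.7, 357, 99.2 and 127.6 CPM in the organoid, day-10, day-20 and infected libraries, and Pla2g1b had 1.13, 36.5, 7.69 and 19.3 CPM. Ctrb1 was highest in the organoid, with 147, 26.5, 38.7 and 1.24 CPM. Cela1 had 13.8, 20.1, 21.5 and 28.7 CPM. Gip had 1116 counts in the organoid library, 96.6% of them in 1 cell, and 0% in cells annotated as enteroendocrine.

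Enteroendocrine cells had a larger share in the day-10 mini-gut than in the organoid library. The range of detected genes per cell, which differs between libraries, does not account for this: among day-10 cells in the organoid range of detected genes, 49 of 717 were enteroendocrine, with a lower bound of 5.10%, above the organoid upper bound of 0.876%. UMIs per cell were not matched: the organoid cells began at 10795 UMIs, while the day-10 enteroendocrine cells had a median of 9585. A difference between libraries in a cut on UMIs was not tested. For free RNA counted in other cells, 99.3% of the Chgb counts lay in cells annotated as enteroendocrine, which met the bound set against it. Chgb leads the genes of that class, so a cell named through free RNA would be counted there too. This test therefore cannot decide whether free RNA contributes. The culture format may be the cause, since the lowest share in any of the 3 mini-gut libraries was 4.91%. With 1 organoid library, the format cannot be told apart from other differences of that library.

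Interferon response transcripts were higher in the infected than in the day-10 mini-gut. The tables argue against a change in the mixture of classes, as the median within ISC was 2.12, though it was 0.83 in the 305 infected ISC outside a cluster led by interferon-induced genes and a shift between states within ISC was not tested. They argue against the library's dissociation stress, as the median was 1.84 among 275 ISC per library matched on stress transcripts, whose own median went from 0.74 to 0.09. They also argue against depth and the range of detected genes, with a median of 2.21 in the shared range. A library difference unrelated to infection stays open, since there is no replicate; the list also differed by 0.54 between the uninfected mini-guts of different age. A response to infection is a hypothesis that these data cannot separate from that difference.

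Fabp6 and Slc51b were higher in the infected than in the day-10 mini-gut. They did not move together over the uninfected libraries. In the organoid, day-10, day-20 and infected libraries, Slc51b had 778, 67, 279 and 664 counts, and Fabp6 had 25, 1, 2 and 1257. A high Slc51b level is thus not particular to the infected library. A change in the mixture of the authors' classes alone does not account for the difference between the infected and day-10 mini-guts. Within Enterocytes and TopEnterocytes, Fabp6 had 1222 counts against 0, with an exact 95% lower bound of the ratio of 445. That bound covers counting error only, and the top cell held 30.1% of the infected library's Fabp6 counts. Enterocytes also differed in their clusters: cluster 11 held 27 of 100 infected and 19 of 155 day-10 ones, and cluster 7 held 22 and 98. A shift between states within Enterocytes was not tested. A more distal identity of the culture stays open: the median log2 ratio of 6 other distal genes, 0.26, met the bound of 0.5 first set against it, but that bound was set aside after the value was seen, because 2 of the 6, Cubn (5.47 CPM against 1.67) and Muc3 (44.8 against 18.6), were at least 1.5-fold higher and a median over all cells dilutes genes of few enterocytes. Exposure to an activator of FXR, the bile acid receptor that induces both genes, may be a cause: summed counts of its targets Nr0b2 and Fgf15 were 106 against 24, a ratio of 5.46 (3.48 to 8.90), above the bound of 2 set in advance. Both targets are also ileal genes, so this test does not separate FXR activation from distal identity.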
